A study of Mus musculus with 2 samples.

How the data were processed

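Liver RNA from mice was measured on 2 single-colour Affymetrix arrays, 1 per group. Each array was hybridised with biotin-labelled cRNA made from RNA that had been pooled from 3 livers. The groups were mice given antagomir-122 and mice given the scrambled control called mm-antagomir-122. An antagomir is a chemically modified, cholesterol-linked oligonucleotide complementary to a microRNA, and miR-122 is a microRNA that is abundant in hepatocytes. Both groups received 80 mg/kg per day on 3 days and were sampled 24 h after the last injection. Each sample was placed in its group by its title.

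The deposited values were linear signal intensities per probe set, made with MAS5 per the submitters' processing notes. No MAS5 version was given. The 2% trimmed mean of all 45101 probe sets was 500.0 on both arrays, so the authors' values had been scaled to a common target. No detection calls, probe-level values or array replicates were used here. MAS5 intensities carry a relative error that grows as the signal falls, and without detection calls a dim value cannot be told from background.

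Gene names came from the array's platform annotation, which can be old, with symbols looked up by gene identifier in the RefSeq gene table of GRCm38.p6. Of the probe sets, 64 were Affymetrix controls, 34945 had 1 gene, 932 had several genes and 9160 had no gene name in the annotation used here. The lookup found 34741 of the 34945 probe sets and changed 0 symbols. Probe sets with several genes or none were not used for genes. No genome coordinates are given, because the files name no build. Fixed list members without a single-gene probe set were not analysed here. The 2 miR-122 target lists and the pathway lists were written from general knowledge.

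The ratio of a gene was log2 of the antagomir-122 intensity over the control intensity, as deposited and with no pseudocount. A gene was kept if a probe set of that gene had a mean log2 intensity at or above the 60th percentile of the non-control probe sets, which was a signal of 238. That left 16023 probe sets of 10003 genes. Each gene was represented by its brightest probe set. With 1 array per group there was no replicate error, so no test between the conditions was run and no p-value is given. Sizes of change are described by a threshold of 1.5-fold. The words higher and lower refer to the antagomir-122 pool relative to the control pool.

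Measurement spread was estimated from 3860 genes with a second probe set above the floor. The SD of the difference between the log2 ratios of the brightest and second probe sets, divided by the square root of 2, was 0.28. It includes real differences between transcripts of one gene and leaves out the spread between animals. These differences were drawn again among genes of like signal, 100 times, to count genes that measurement spread alone would carry past 1.5-fold. After seeing the data, the draws were repeated with the ratios after quantile normalization and loess correction.

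A total of 31 gene lists were fixed before the data were examined, with 448 memberships, of which 349 were in the background of 10003 genes. For each list with at least 4 such genes, the median log2 ratio was placed among the medians of 10000 random lists of equal size, matched on mean signal in 20 bins. A list outside the central 95% of these medians was called high or low. Of 28 lists, about 1.4 would lie outside these limits by chance. The random lists hold genes that need not move together, so percentiles of co-regulated lists are descriptions of these 2 arrays. The gene-naming rule, also fixed before the data were examined, took the 12 highest and 12 lowest genes whose probe sets above the floor did not disagree in sign, leaving out Riken, Gm, LOC and EST names and antigen receptor segments. It also took up to 4 members of each list with the largest change, every measured member of the cholesterol list and of the miR-122 target lists, and the housekeeping genes. Genes named outside the rule are marked as such.

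The calculation was tested on simulated data built from the 10003 genes and the measured spread. Of 200 planted genes, 51.5% passed 1.5-fold when planted at 1.5-fold, 93% when planted at 2-fold and 100% when planted at 3-fold. Of 200 simulated unchanged lists of 15 genes, 3% lay outside the limits. Alternatives were median centring, quantile normalization, a loess correction with a span of 0.3, floors at the 40th and 80th percentiles, a pseudocount of 37.8, the mean over probe sets, leaving out probe sets with the suffixes _s, _x and _a, and thresholds of 1.4-fold and 2-fold. Scaling on the hybridization controls, counting only genes with a second probe set that moved the same way, and setting signals under the floor to the floor, were added after seeing the data. Folds of named genes with 1 signal under the floor are given against the floor, as lower bounds. These bounds account for the floor only and leave out the measurement spread of the other signal. List medians were also computed without members above a signal of 16000 on both arrays, a limit chosen after seeing the data. A planned search for miR-122 seed matches in 3' UTRs was not run, since no transcript sequences were used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.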

Results

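The question addressed was which liver transcripts differ in mice given an oligonucleotide against miR-122. One pooled array per group was compared, so every value below describes a pool of 3 livers on 1 array. Signals ran from 0.1 to 34477 on the antagomir-122 array and from 0.1 to 34506 on the control array. The median signals were 172 and 156. The spread between probe sets of the same gene was 0.28 on the log2 scale, or 1.21-fold (3860 pairs). It was 0.35 over 589 pairs among the dimmest 3335 of the 10003 genes, and 0.23 over 1813 pairs among the brightest 3335.

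The median log2 ratio of 11 housekeeping genes was 0.03. On their brightest probe sets Actb, Eef2, B2m, Rplp0, Ywhaz, Hprt, Sdha, Tbp, Gusb and Pgk1 lay within 1.07-fold, and Polr2a was 1.47-fold higher. Actb, B2m, Eef2, Pgk1 and Rplp0 had signals above 16000 on both arrays, where the top of the range can hide a difference, and the other 6 genes had a median of 0.02. Another probe set of Ywhaz had a log2 ratio of 1.03, and scaled on the hybridization controls described next all 11 genes lay above 0. The probe sets for bacterial and phage hybridization controls, which are spiked into the sample, did differ. Whether the spiked amount or the amount of liver cRNA differed between the arrays is not known here. Their median log2 ratio was -0.27 (SD 0.18 over 18 probe sets), and 17 of the 18 were lower on the antagomir-122 array. These probe sets repeat the same few transcripts (bioB, bioC, bioD and cre), so they are not 18 independent readings. Scaling on these controls would add 0.27 to every log2 ratio. All directions below are therefore relative to the bulk of the genes, whose median log2 ratio was 0.00 as deposited.

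Among the 10003 genes, 512 were at least 1.5-fold higher and 262 at least 1.5-fold lower in the antagomir-122 pool. At 2-fold the counts were 83 and 31. Higher genes made up 66.1% of those past 1.5-fold as deposited, and 96.4% when scaled on the hybridization controls (1693 higher and 63 lower). Measurement spread alone put 270 genes past 1.5-fold upwards (range 230 to 316 in 100 draws) and 269 downwards (238 to 309). As deposited the higher count exceeded this range and the lower count did not. With quantile normalization 457 were higher and 322 lower, against highest counts of 306 and 304 in draws from those ratios. With loess correction 456 were higher and 326 lower, against 316 and 306. These draws hold no spread between animals. They also include the spread of the second probe set, always the dimmer of the pair, so they may overstate that of the brightest. A count inside the range therefore does not show that those genes differ by measurement spread alone. Of the higher genes, 161 had a second probe set above the floor, which was also higher in 125 (77.6%, 95% Wilson interval 70.6 to 83.4) and at least 1.5-fold higher in 40. Of the lower genes, 70 had one, which was also lower in 54 (77.1%, 66.0 to 85.4) and at least 1.5-fold lower in 19. These intervals cover counting error over genes only. Of the genes named here, 61 had several probe sets above the floor. Of 15 past 1.5-fold on the brightest, 7 had another that was not, and of the remaining 46, 11 had another that was past it in the same direction.

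**Figure D1:**
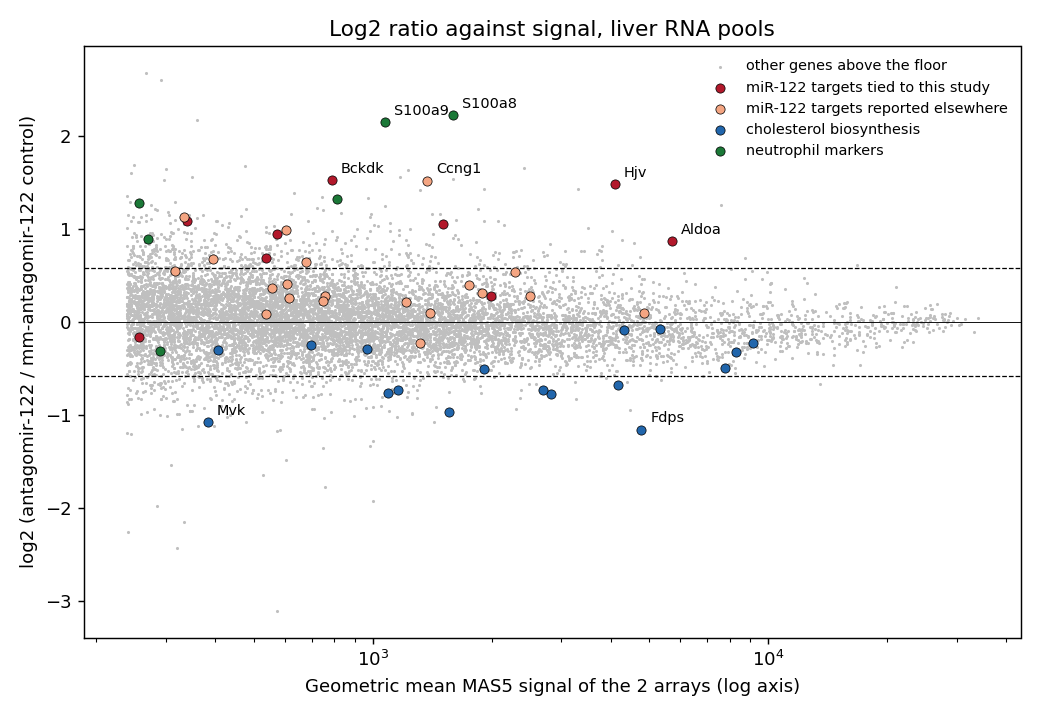
Log2 ratio of the antagomir-122 pool over the control pool (y axis) against the geometric mean signal of the 2 arrays (x axis, log scale) for 10003 genes, 1 point per gene, with 4 gene lists coloured and dashed lines at 1.5-fold. With the deposited scaling the cholesterol biosynthesis genes lie below 0, and 8 of 9 and 19 of 20 members of the miR-122 target lists lie above it; scaled on the hybridization controls, 4 of the 17 cholesterol genes lie above 0.

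The genes with the highest ratios of deposited signals included transcripts of several kinds. Where the dimmer signal of a gene lay under the floor, the fold was taken against the floor and is given as at least that size, so the order of such genes is not settled. S100a8 and S100a9, which encode calcium-binding proteins abundant in neutrophils, were 4.66-fold and 4.42-fold higher. Noct (nocturnin, a clock-output enzyme) was 2.94-fold higher, at signals of 2007 and 682. Cda, a cytidine deaminase, was 3.10-fold higher, and Inhbb, a subunit of inhibin and activin, was at least 2.22-fold higher. Mup10, of the major urinary protein family, was at least 3.21-fold higher, and its value is uncertain because the members of that family are nearly identical. Pde6c was 3.19-fold higher. G6pc3 was at least 3.01-fold higher, Clec2d at least 2.84-fold, Smo at least 2.51-fold, Zfp213 at least 1.87-fold and Pou5f2 at least 1.78-fold. Each of these 12 genes rested on 1 probe set above the floor, and for 7 of them the control signal was under the floor. Another probe set of Smo had signals of 194 and 213, both under the floor.

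The genes with the lowest ratios included Acacb, an acetyl-CoA carboxylase of fatty acid metabolism, which was at least 2.21-fold lower (signals 110 and 526). Serpina7, which encodes thyroxine-binding globulin, was 3.43-fold lower, and the lipid phosphatase gene Inpp5j was 3.80-fold lower. Slc22a27 and Slc22a29, organic anion transporter genes, were 2.53-fold and 2.56-fold lower, each on a probe set that can cross-hybridise, and as near-identical paralogs they are uncertain. Ercc1 was at least 3.12-fold lower on its brightest probe set, which carries the suffix _s and can cross-hybridise. On its second, without a suffix, it was at least 1.37-fold lower. Pcnt was 3.14-fold lower and Fzd8 2.80-fold. Snai2 was at least 2.95-fold lower, on a probe set that can cross-hybridise. Ddx28 was at least 2.36-fold lower, Bcs1l at least 1.56-fold and Cnmd at least 1.52-fold. Of these 12 genes, 11 rested on 1 probe set above the floor, and for 6 the antagomir-122 signal was under it.

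Reported targets of miR-122 were higher in the antagomir-122 pool. Of 9 measured genes remembered as targets from these or closely related antagomir experiments, 7 were at least 1.5-fold higher and 0 were 1.5-fold lower. The median was 1.93-fold higher (log2 0.95), above all 10000 matched random lists, whose central 95% ran from -0.22 to 0.25. Bckdk, the kinase of branched-chain ketoacid dehydrogenase, was 2.88-fold higher, at signals of 1338 and 465. Hjv (formerly Hfe2), the hemojuvelin gene of iron regulation, was 2.79-fold higher on its brighter probe set, and its probe sets had log2 ratios of 1.47 and 1.48. The collagen prolyl hydroxylase subunit gene P4ha1 was at least 2.07-fold higher, Tmed3 2.07-fold and Cd320 1.93-fold. Aldoa, the aldolase of muscle and other non-liver tissues, was 1.83-fold higher, and its 5 probe sets had log2 ratios from 0.79 to 1.17. All 5 carry the suffix _x and can cross-hybridise, so their agreement is not independent. Ndrg3 was 1.61-fold higher and Iqgap1 1.21-fold higher on their brightest probe sets, while another of Ndrg3 had a log2 ratio of 1.54 and those of Iqgap1 had 0.39 and 0.65. Slc7a1, a cationic amino acid transporter gene, had a log2 ratio of -0.17 near the floor (signals 242 and 271). Gys1 was under the floor and so outside the list. Its signals were 371 and 40.3 on one probe set, at least 1.56-fold higher, and 54.6 and 22.1 on the other. Of 49 list members under the floor, 2 were at least 1.5-fold from it, Gys1 and the cholangiocyte marker Epcam given with its list, and both were chosen after their values were seen. This list was chosen at least in part on these samples and is not independent evidence of its direction.

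A second list held targets reported in other work. Of its 20 measured genes, 19 had a ratio above 0, 5 were at least 1.5-fold higher and 0 were 1.5-fold lower. The median was 1.26-fold higher (log2 0.34), above all 10000 random lists, whose central 95% ran from -0.14 to 0.16. Ccng1, which encodes cyclin G1, was 2.86-fold higher on its brightest probe set. Its 3 probe sets had log2 ratios of 1.52, 0.99 and 0.37, with a mean of 0.96. Once the suffixed probe set was left out, the ratio was 0.37, from the brighter of the other 2. Gpx7 was at least 2.08-fold higher, Agpat1 1.98-fold, Ccn2 (connective tissue growth factor) 1.60-fold and the metalloprotease gene Adam17 1.56-fold. The other probe sets of Adam17 had log2 ratios of 0.25 and 0.35. Sprr1a and Adam10 had log2 ratios of 0.55 and 0.54, and Foxj3, Mapre1, Klf6 and Ptpn1 had log2 ratios of 0.41, 0.40, 0.36 and 0.31. Those of Clic4, Bcl2l2, Cux1, Srf and Prkab1 were 0.28, 0.27, 0.26, 0.23 and 0.21. Other probe sets of Clic4 had 0.68 and 0.71, one of Mapre1 had 0.62, and that of Srf was at least 1.90-fold higher. With the mean over probe sets 17 of the 20 genes lay above 0, and 5 were at least 1.5-fold higher, with Srf (0.63) in place of Adam17 (0.41). Rhoa, Gtf2b and Igf1r had 0.10, 0.09 and 0.08, and Pkm had -0.23. Other probe sets of Prkab1, Rhoa and Igf1r went the other way. Leukocyte and macrophage markers were also higher in this pool, with a median of 0.46 over 26 genes.

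Genes of cholesterol biosynthesis were lower together. All 17 measured enzymes had a ratio below 0 as deposited, but with quantile normalization 1 lay above 0, and scaled on the hybridization controls 4 did. The median was 1.42-fold lower (log2 -0.50), below all 10000 random lists, whose central 95% ran from -0.18 to 0.10. Of the 17, 8 were at least 1.5-fold lower as deposited and 3 when scaled on the hybridization controls. Fdps, farnesyl diphosphate synthase, was 2.23-fold lower (signals 3201 and 7138). Mvk, mevalonate kinase, was 2.10-fold lower, and Dhcr7, the enzyme of the last step to cholesterol, was 1.96-fold lower. Nsdhl was 1.71-fold lower, Lss 1.69-fold, Sqle (squalene epoxidase) 1.66-fold, Idi1 1.65-fold and Fdft1 (squalene synthase) 1.59-fold. Cyp51 and Hmgcs1 each had a log2 ratio of -0.50 on the brightest probe set, and the others had -0.60 for Cyp51 and -0.61, -0.79 and -0.89 for Hmgcs1. Those of Ebp, Mvd, Hsd17b7, Pmvk and Sc5d were -0.33, -0.31, -0.29, -0.25 and -0.23, and those of Tm7sf2 and Msmo1 were -0.09 and -0.07. Another probe set of Hsd17b7 had -0.84, and probe sets of Sc5d disagreed, from -0.23 to 0.85. With the mean over probe sets 9 genes were at least 1.5-fold lower, Hmgcs1 among them, and Sc5d lay above 0 (0.31). This pathway is known to have been reported from these arrays, so the list is not independent evidence of its direction.

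The other sterol genes did not stand apart. For 11 regulators and transporters of sterols the median log2 ratio was -0.02, at percentile 69.6. Stard4 and Srebf1 had log2 ratios of -0.34 and -0.33, and Nr1h3 (liver X receptor) and Mylip had 0.18 and 0.16. Lipogenic genes had a median of -0.06 over 16 genes, at percentile 41.0, with Acacb past 1.5-fold on the brightest probe sets. Me1, Fads1 and Scd1 had log2 ratios of -0.58, -0.55 and -0.46. Other probe sets of Me1 and Fads1 went the other way, and that of Scd1 had -1.14, which puts the mean of its probe sets at -0.80. Genes of fatty acid oxidation and PPARα response were low as a list, with a median of -0.23 over 15 genes at percentile 0.19. Scaled on the hybridization controls the median turned to 0.04, while the percentile stayed at 0.19 because every gene shifts alike. Of these, 1 was at least 1.5-fold lower, namely Vnn1 (pantetheinase), which was 1.66-fold lower. Acadl and Ehhadh, enzymes of β-oxidation, had -0.54 and -0.46, while Pdk4 had 0.40.

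Bile acid genes as a list had a median of 0.01 over 16 genes, at percentile 87.4, with 8 members above 0 and 8 below. On the brightest probe sets 3 members were at least 1.5-fold higher and 0 at least 1.5-fold lower. Cyp8b1, the sterol 12α-hydroxylase, was 2.24-fold higher. The transporter gene Slco1a1 was 1.83-fold higher, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.53-fold higher. Another probe set of Cyp7a1 had a log2 ratio of 0.27, and their mean of 0.44 was under 1.5-fold. Cyp7b1 had a log2 ratio of 0.58. Xenobiotic metabolism genes had a median of 0.07 over 15 genes at percentile 98.3, a call lost with quantile normalization (percentile 93.9). Without 7 members above 16000 on both arrays the median was 0.16 (percentile 98.2). Cyp2b10, a target of the CAR receptor, was 1.54-fold higher. Gstm3 and Cyp1a1 had log2 ratios of 0.54 and 0.40, and Gsta2 had -0.52.

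Markers of leukocytes and macrophages were higher in the antagomir-122 pool. Of 6 measured neutrophil markers, 5 were at least 1.5-fold higher, with a median log2 ratio of 1.30, above all 10000 random lists. Besides S100a8 and S100a9, the granule gene Ngp was 2.49-fold higher and Mpo at least 1.68-fold higher. The member that was not, Elane, named after its value was seen, had a log2 ratio of -0.31. With signals under the floor set to the floor, the median of this list was 1.03. All 12 Kupffer cell and macrophage markers had ratios above 0 as deposited and with quantile normalization and loess correction. They also did with median centring and scaling on the hybridization controls. Those 2 scalings do not test the direction, since they lower every ratio by 0.0027 and raise it by 0.27. The median of the 12 markers was 0.40 as deposited, above all 10000 random lists. C1qc, a complement subunit, was 1.61-fold higher and Adgre1 (F4/80) 1.52-fold, while Cd68 and Lyz2 had log2 ratios of 0.50 and 0.46. The 8 lymphocyte markers had a median of 0.49, at percentile 99.9, and all lay above 0 as deposited but 7 did with quantile or loess correction. Ighm was 2.13-fold higher on its brightest probe set (0.08 to 1.09 over 4 probe sets), Nkg7 1.60-fold and Ms4a1 1.59-fold, and Ptprc (CD45) had 0.51.

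Markers of other non-hepatocyte cells did not stand apart. The median was 0.04 for 12 endothelial markers (percentile 76.2) and 0.01 for 12 stellate and fibroblast markers (percentile 63.4). Tek was 1.66-fold lower, Kdr, Eng and Stab1 had log2 ratios of -0.31, -0.28 and 0.28, and Col1a1, Acta2 and Reln had 0.44, 0.42 and 0.30, with another probe set of Col1a1 at 0.86. Des was at least 1.30-fold lower. Another probe set of Eng had 0.13. Too few cholangiocyte, erythroid and exocrine pancreas markers were above the floor for a percentile. Of the cholangiocyte markers, Tspan8 and Anxa3 had 0.31 and 0.24. Epcam, under the floor by its mean, was at least 3.50-fold lower on one probe set (signals 37.1 and 834), which carries the suffix _x and can cross-hybridise. It was at 33.6 and 30.3 on the other. The erythroid markers Car2 and Alas2 had -0.34 and 0.08, and the exocrine pancreas marker Cela1 had 0.15. Hepatocyte products and regulators had a median of -0.01 over 14 genes (percentile 79.7), with Apoc3, Apob and Cebpa at 0.14, -0.10 and -0.08 and another probe set of Apob at 0.34. Of these genes 9 had signals above 16000 on both arrays, and the other 5 had a median of -0.07. Ass1 was 2.17-fold lower on a dim probe set, but a bright probe set shared with Gm5424 had a log2 ratio of -0.01.

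**Figure D2:**
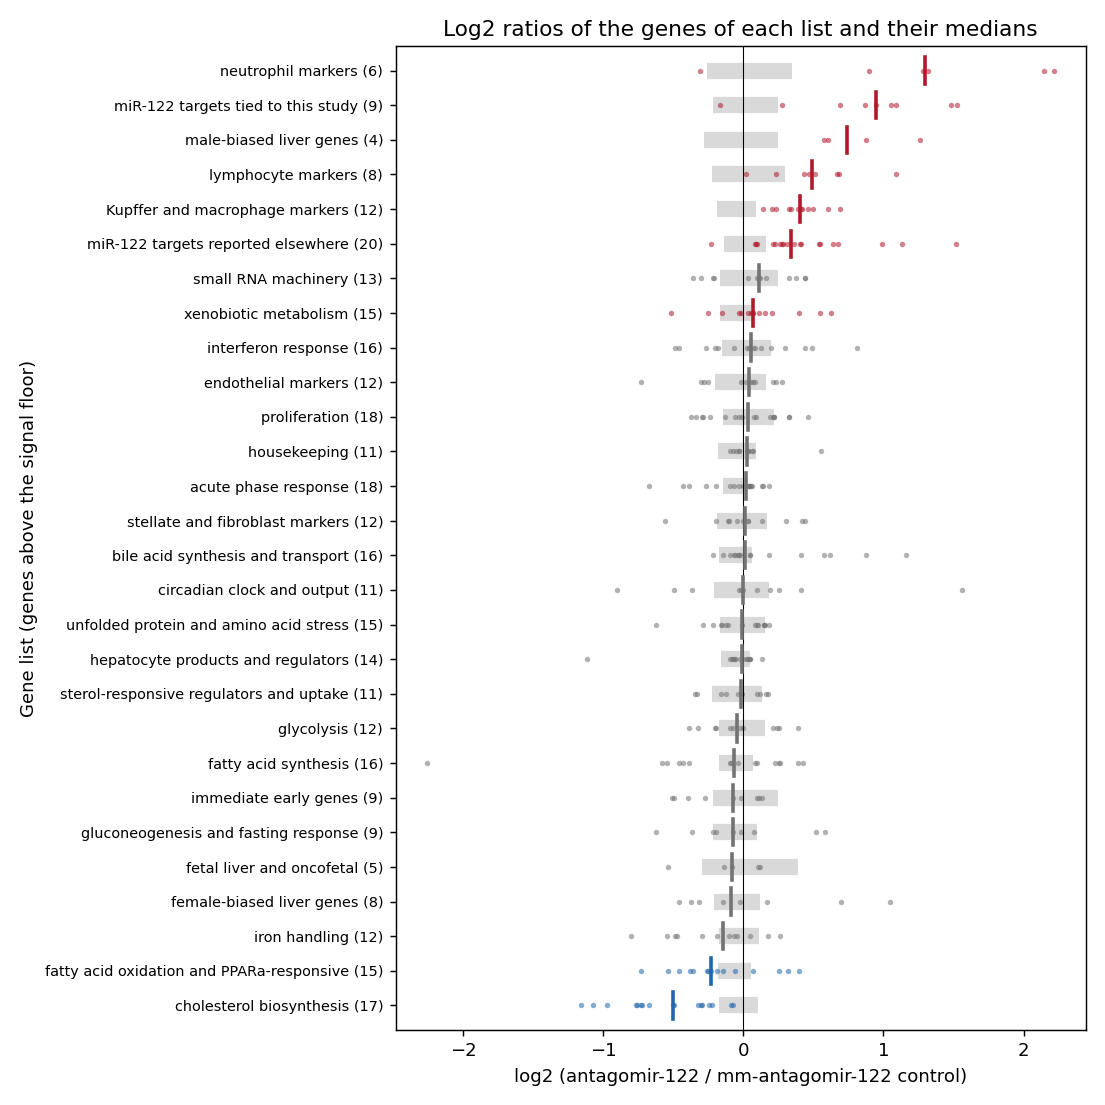
Log2 ratio of the antagomir-122 pool over the control pool, as deposited (x axis), for the genes of each of 28 fixed lists (y axis, genes above the floor in parentheses). Points are genes, vertical ticks are medians, grey bars are the central 95% of 10000 signal-matched random lists, red marks 7 lists above that range and blue 2 below it. The fatty acid oxidation median turns to 0.04 when scaled on the hybridization controls, with its percentile unchanged.

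Of the remaining lists, 1 stood outside the limits. The 4 measured male-biased liver genes had a median of 0.74, at percentile 99.99, and 3 were at least 1.5-fold higher. The list had 10 members with a single-gene probe set, and the rest were under the floor. Among these, Hsd3b5 had signals of 7.3 and 6 and Cyp4a12a 227 and 182. Both were named outside the rule, after their values were seen. Of the measured genes, Cyp2d9 was 2.40-fold higher (signals 11790 and 4919) and Mup3 1.52-fold, both in families of near-identical genes. The other 2 measured genes, Slco1a1 and Cyp7b1, were also in the bile acid list. Female-biased genes had a median of -0.09 over 8 genes (percentile 33.2), which turned to 0.19 when scaled on the hybridization controls and was called low with the mean over probe sets (-0.22, percentile 2.16). Among them were Cyp17a1 2.06-fold and Xist 1.62-fold higher and Sult2a2 and Acot3 at -0.46 and -0.37, with another probe set of Xist at 0.23.

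Stress, inflammation and growth lists lay inside the limits as deposited. The medians of 13 lists inside the limits changed sign under at least 1 alternative other than the hybridization controls, so their signs are given as values only. The acute phase list had a median of 0.02 over 18 genes (percentile 95.2), with Orm2 1.59-fold lower and Socs3, Apcs and Orm1 at -0.43, -0.39 and -0.26, and another probe set of Socs3 at -0.75. Of the 18, 12 had signals above 16000 on both arrays, so the list median does not show that the response was unchanged, and the other 6 had a median of -0.17 (percentile 8.69). The interferon list had 0.06 over 16 genes (percentile 68.7), with Oasl1 at least 1.74-fold higher, Ifit1 and Bst2 at 0.49 and -0.49 and Ifit2 at least 1.18-fold lower. The unfolded protein and amino acid stress list had -0.01 over 15 genes (percentile 55.8), with Sdf2l1 1.54-fold lower and Trib3, Hsp90b1 and Creld2 at -0.29, -0.21 and 0.18, and another probe set of Trib3 at -0.76. Immediate early genes had -0.07 over 9 genes (percentile 24.5). Junb, Zfp36, Myc and Dusp1 had -0.51, -0.50, -0.40 and -0.28. With the mean over probe sets, this list lay at percentile 0.54. Proliferation genes had 0.03 over 18 genes (percentile 51.9), with Ccnb2, Ccne1, Mcm6 and Mki67 at 0.46, -0.38, -0.34 and 0.33 and another probe set of Ccne1 at least 1.75-fold higher. Fetal liver genes had -0.08 over 5 genes (percentile 22.3), with Mest, Igf2bp3, Peg3 and Cd24a at -0.54, -0.14, 0.12 and 0.11.

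Metabolic and regulatory lists also lay inside the limits. Glycolysis had -0.05 over 12 genes (percentile 32.5), and 0.23 over 6 genes (percentile 95.5) without suffixed probe sets, with Hk2, Pgam1, Tpi1 and Pfkm at 0.39, -0.39, -0.32 and 0.25. The gluconeogenesis and fasting list had -0.07 over 9 genes (percentile 43.9). Igfbp1 was 1.54-fold lower, and G6pc, Foxo1 and Got1 had 0.58, 0.52 and -0.37, with another probe set of Foxo1 at -0.09. Clock genes had -0.01 over 11 genes (percentile 57.8). Besides Noct, Nr1d1 (REV-ERBα) was 1.87-fold lower, and Dbp and Per2 had -0.49 and 0.41, with another probe set of Per2 at -0.21. Iron genes had -0.15 over 12 genes (percentile 5.82). Smad7 was 1.74-fold lower, and Id1, Tfrc and Slc11a2 had -0.54, -0.49 and -0.47. Another probe set of Tfrc had 0.23. Of Slc11a2, another had -0.52, while a further one was at least 2.64-fold higher and the mean was 0.14. Without 2 members above 16000 on both arrays, a choice made after seeing the data, the iron median was -0.24 (percentile 0.51), while it was -0.0448 (percentile 47.8) with the mean over probe sets and -0.0672 (percentile 30.9) without suffixed probe sets. Small RNA genes had 0.11 over 13 genes (percentile 75.7), with Ago2, Tnrc6a and Drosha at 0.44, 0.44 and 0.38 and Ago3 at signals of 223 and 285, and probe sets of Ago2 and Tnrc6a disagreed in sign.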

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

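The comparison with named genes of like signal was chosen after the data were seen. Probe sets without a gene name took part in no comparison above. Of 1483 such probe sets above the floor, 31 were at least 2-fold higher in the antagomir-122 pool and 9 at least 2-fold lower. At 1.5-fold the counts were 164 and 38, and the median log2 ratio was 0.11. Named genes drawn at matched signal gave 103 probe sets past 1.5-fold upwards on average and at most 134 in 1000 draws, and a median of 0.03. Downwards they gave 51.2 on average (range 33 to 72), a range that holds the 38 observed. At 2-fold the same draws gave 17.6 on average and at most 32. The highest of the unnamed probe sets had signals of 1386 and 261 (5.32-fold).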

How the results depend on the processing

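No paired analysis was possible because there was 1 array per group. No replicate could be left out and no other split of samples was possible, and the planned 3' UTR seed-match results with their alternatives were not run. The count of genes at least 1.5-fold higher (512 as deposited) was 1163 with the floor at the 40th percentile, 184 with it at the 80th, 816 at 1.4-fold and 83 at 2-fold. For lower genes (262) these values were 531, 98, 485 and 31. Scaled on the hybridization controls, an alternative chosen after seeing the data, the counts were 1693 and 63. With only genes whose second probe set moved the same way, also chosen after seeing the data, they were 125 and 54. With signals under the floor set to the floor, again chosen after seeing the data, they were 454 and 235, and neutrophil markers had a median of 1.03. The hybridization controls also moved the medians of the lists outside the limits, since 0.27 is added to every gene. The cholesterol list was then at -0.23, the target lists at 1.22 and 0.61, Kupffer markers at 0.68, lymphocyte markers at 0.76, neutrophil markers at 1.57, male-biased genes at 1.02 and xenobiotic genes at 0.34, and fatty acid oxidation turned to 0.0419. The percentiles of these lists did not change, since every gene moved alike. Fewer or other probe sets moved medians too. With the mean over probe sets cholesterol was at -0.63, sterol regulators at -0.11, immediate early genes at -0.28, iron genes at -0.0448, small RNA genes at -0.0256 and female-biased genes at -0.22. Without suffixed probe sets cholesterol was at -0.73, lipogenesis at 0.0230, glycolysis at 0.23, the stress list at 0.10 and iron genes at -0.0672. Quantile normalization gave lipogenesis 0.0589, fatty acid oxidation -0.14, bile acid genes 0.10, the fasting list 0.0265 and female-biased genes 0.00399. Loess gave lipogenesis 0.00197, fatty acid oxidation -0.17, bile acid genes 0.0784, hepatocyte products 0.0684, acute phase 0.11 and xenobiotic genes 0.15. Small RNA genes were at 0.28 with the floor at the 80th percentile, and male-biased genes at 0.59 with it at the 40th. The next tally counts scaling on the hybridization controls only for lists outside the limits. That scaling moved the other lists by 0.27 too, more than the SD of their random lists. Of 255 list values under an alternative so counted, 221 moved by less than the SD of their random lists. In 3 cases a list changed its side of the percentile limits: xenobiotic genes with quantile normalization, and immediate early and female-biased genes with the mean over probe sets. The cause was not tested. Without members above a signal of 16000 on both arrays, also chosen after seeing the data, medians were -0.21 for fatty acid oxidation (percentile 0.61), 0.05 for bile acid genes (93.9), -0.03 for glycolysis (41.4) and -0.14 for the fasting list (18.8). Of 1016 values for 176 named genes, 990 moved by less than 0.28, 26 moved further (19 of them towards 0) and 0 of those past 1.5-fold turned direction. This tally leaves out the setting of signals under the floor to the floor, which took Clec2d from 6.38-fold to 2.84-fold higher. Dim genes had the least certain ratios, with a spread between probe sets of 0.35.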

Other observations

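Gene families were grouped by symbol stem after the data were seen, giving 249 families of at least 6 genes, of which about 6.23 on each side would lie outside the limits by chance. Below the limits were 15 families, named Cfap, Commd, Dhx, Fbxl, Med, Mettl, Mrpl, Mrps, Ndufb, Ndufs, Nup, Rps, Snhg, Socs and Thap. Of the mitochondrial ribosomal protein genes, 35 of 47 Mrpl and 24 of 29 Mrps had ratios below 0 as deposited, with medians of -0.22 and -0.24. All 9 Ndufb genes and all 6 Ndufs genes, which encode subunits of respiratory complex I, lay below 0 as deposited (medians -0.27 and -0.40), as did all 12 Ndufa genes, whose median of -0.14 lay inside the limits (percentile 11.1). With quantile normalization 8 of the 12 Ndufa genes lay below 0 (median -0.05), and with loess correction 10 did (-0.07). Rps genes of the cytosolic ribosome had a median of -0.16 as deposited, -0.09 with quantile normalization and -0.08 with loess correction, and Rpl genes, inside the limits, had -0.09 (percentile 20.1). With quantile normalization and loess correction, 0 of the 15 medians turned above 0. Median centring, which lowers every ratio, could not turn them. Scaling on the hybridization controls adds 0.27 to every gene and so turns any median between -0.27 and 0, which held for 13 of the 15.

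Above the limits were 14 families, named Adam, Adcy, Anxa, Ccl, Cd, Ces, Clec, Csf, Cxcl, H2, Ms4a, Pip, Slc and Tmed. With quantile normalization and loess correction, 0 of their medians turned below 0. Median centring lowers every ratio by only 0.0027 and the hybridization controls raise it, so those scalings could not turn them. Genes named Cd with a number had a median of 0.22 over 44 genes, and Ms4a genes 0.46 over 9. The medians were 0.54 for 6 Adcy genes, which encode adenylyl cyclases, 0.37 for 10 Adam genes and 0.19 for 14 H2 genes of the major histocompatibility complex. The Il, Ifi, Tlr and Gimap families lay inside the limits, at percentiles 91.8, 91.9, 68.1 and 49.1. Xist, transcribed from the inactive X chromosome, had signals of 6030 and 3723. The brightest probe sets of the Y-linked genes Uty, Kdm5d and Eif2s3y were at 180, 118 and 42.3 in the antagomir-122 pool and 51.5, 77.6 and 36.6 in the control pool, all under the floor of 238. These 3 Y-linked genes were named outside the rule, after their values were seen.

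The loess tests in the following paragraphs were written before their results were seen. The tests of feeding, time of day, cell share, blood and RNA integrity were chosen after seeing the data.

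Cholesterol biosynthesis genes had a median of -0.50 over 17 genes, and a signal-dependent trend between the arrays is argued against, since it was -0.47 after loess correction. Less feeding stays open. The median of 16 lipogenic genes, which are known to be lower on fasting, lay 0.44 above that of the cholesterol genes. The lipogenic genes went both ways, however (7 above 0 and 9 below), with an SD of 0.64. The gluconeogenesis and fasting list was not high (median -0.07, percentile 43.9), with Igfbp1 1.54-fold lower but G6pc at 0.58. The fatty acid oxidation and PPARα list was low (-0.23, percentile 0.19), with 11 of 15 genes below 0 but Pdk4 at 0.40. That median turned to 0.04 when scaled on the hybridization controls, but its percentile stayed at 0.19, since every gene shifts alike. Members of both lists went both ways, so neither list was taken to decide the question. A difference in time of day stays open. The median absolute change of 10 clock genes without Noct lay at percentile 70.4. Noct, left out of that test, had the largest change of the list (2.94-fold higher). Nr1d1 was 1.87-fold lower. Arntl, named outside the rule after its value was seen, was under the floor by its mean, with signals of 280 in the antagomir-122 pool and 166 in the control pool. An effect of the antagomir may be the source, and the design, with 1 pool per group, cannot separate it from differences between the pooled animals.

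The higher leukocyte and macrophage markers, with a median of 0.46 over 26 genes of 3 lists, could come from more of these cells or from a technical source. A signal-dependent trend is argued against, since the median was 0.51 after loess correction. A lower hepatocyte share that raises all other cell types is argued against, because the leukocyte median lay 0.44 above that of 24 endothelial and stellate markers (SD of these 24 markers 0.28). More blood in the tissue cannot be told apart, because only 2 erythroid markers were above the floor. A response to the antagomir may also account for it and was not tested, since it cannot be separated from differences between the pooled animals.

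The mitochondrial ribosomal protein genes, lower relative to the bulk of the genes, kept a median of -0.19 after loess correction, which argues against a signal-dependent trend. A lower hepatocyte share stays open, since 5 hepatocyte genes with control signals under 16000 lay 0.15 higher (SD of the difference of medians 0.13). Lower RNA integrity stays open: the ratio of 3' to 5' signal, antagomir-122 pool over control pool, was 1.01 for actin and 1.05 for GAPDH but 1.35 for pyruvate carboxylase. Actin and GAPDH had signals near the top of the range, so their ratios were not taken to exclude it, although the bound set for them was met. An effect of the antagomir may be another explanation and was not tested.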
